A study of Caenorhabditis elegans with 9 samples.

How the data were processed

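The samples were 9 libraries of polyadenylated RNA from whole Caenorhabditis elegans at the L4 stage, 3 each from a control, a hypomethylation and a hypermethylation strain, all in the glp-4(bn2) background. The labels do not state whether the libraries keep the strand, so reads of overlapping genes may be shared: of 350 genes named or listed by rule, 132 overlap another gene and 95 overlap one on the opposite strand. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1, aligned to WBcel235 with HISAT2 2.0.1 and counted per gene with HTSeq 0.6.1. The labels do not say whether replicates are separate cultures, so the p-values measure the spread between these samples.

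The deposited table gives raw counts per gene and library, with no normalisation, for 19986 genes on 6 chromosomes, identified by RefSeq locus tags. The authors also give FPKM, that is counts scaled by exonic gene size and library sum; 100.000% of the deposited FPKM values were within 0.0051 of the value computed from the counts, the gene size and the library sum. Of the genes, 1857 had no count in any library. Transcripts encoded by mitochondrial DNA were not analysed here.

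Groups followed the labels. The choice of test, gene lists, named genes and most alternatives was made before the data were examined. A linear model on FPKM had been planned, with counts to be tested instead if the table held them; since it did, counts were tested and the linear model became an alternative. Genes with a mean of at least 1 FPKM over the 9 libraries were kept, 12300 in all. Counts were scaled by TMM and fitted by edgeR 4.0.16 quasi-likelihood with a mean per group over all 9 libraries, in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison, with no fold minimum. The biological coefficient of variation was 0.185. The 3 comparisons were each strain against control and the strains against each other. TMM factors were 0.872 to 0.896 in control, 0.995 to 1.204 in hypomethylation and 1.01 to 1.036 in hypermethylation. The 10 most abundant genes took 10.62% to 12.13% of counts in control libraries and 4.17% to 5.24% in the strains.

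In all, 41 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They cover mitochondrial, ribosomal, stress, detoxification, immune, cuticle, metabolic, chromatin and signalling genes and cell type markers; a list needed 4 members past the filter. With an estimated correlation, 2, 1 and 0 lists were called in the 3 comparisons, in the order hypomethylation against control, hypermethylation against control and hypermethylation against hypomethylation. The planned test fry was run beside camera. It asks whether a list changes at all, not whether it changes more than other genes. In hypomethylation against control, some lists that missed with camera passed with fry, such as the mitochondrial unfolded protein response (adjusted p = 0.0064). Others, such as cytosolic ribosomal proteins (0.142), did not. Missing the threshold below refers to camera and does not show that a list is unchanged. Counts per list are those over all genes tested, with those adjusted over the list alone beside them for called lists and some others. A list rests on gene symbols, and near-identical copies, among them vit-3, vit-4 and vit-5, share reads that per-gene counts cannot assign.

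Genes were named by rule: alkb-1 and damt-1; for each strain against control the 10 largest rises and 10 largest falls among called genes with a symbol whose libraries did not overlap, and 5 and 5 between the strains; up to 5 per class for genes called in both strains; and up to 4 members of each list with the smallest adjusted p. The text gives part of those. Folds against a group without counts use a floor of 3 counts over the group. Intervals and floors cover counting error only. Overlap between the strains was set against 20 simulated data sets in which unchanged groups shared the controls.

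Depth was 4928732 to 16269812 counts per library, at which 3 counts are 0.609 to 0.184 CPM. Tested on simulated data, the procedure recovered 57%, 46% and 51% of genes changed 2-fold and 10%, 10% and 11% of genes changed 1.5-fold in the 3 comparisons. Of its calls, 9.46%, 5.08% and 7.46% were false (7 of 74, 3 of 59 and 5 of 67). The simulated data held 100 changed genes of each kind among 12300, far fewer than were called in the real data. The adjusted p threshold was therefore stricter there, so these shares do not carry over to the real data.

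Alternatives were limma on log2(FPKM + 1), with other pseudocounts, without trend and robust; TPM; quantile normalisation; median-of-ratios factors; no filter and a filter of 5 FPKM; a replicate block; each pair of groups alone; a 2-fold minimum; DESeq2 1.42.0; and leaving out each library. Scaling by library totals and leaving out the 50 most abundant genes were chosen after seeing the data, as were the Gene Ontology terms and the developmental gene lists. List medians are also given relative to the median of all genes. Scalings that move all genes of a library alike can hardly change that distance, so a sign kept under them is weak support.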

Results

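Polyadenylated RNA was sequenced from whole Caenorhabditis elegans at the L4 larval stage, raised at the restrictive temperature in a glp-4(bn2) background, in which germ cells arrest and, per the labels, no germline develops. The 9 libraries fall into 3 groups of 3: a control strain, a hypomethylation strain overexpressing alkb-1 and a hypermethylation strain overexpressing damt-1. Per the labels, the 2 transgenes encode modifiers of N6-methyladenine in mitochondrial DNA. The comparisons ask how gene expression differs among control and the strains that the labels name for a lowered or raised mark. These libraries do not measure the mark itself. Total counts per library were 12576781, 14482739 and 11783951 in control, 4928732, 15191914 and 11920710 in hypomethylation, and 16269812, 14316530 and 15031668 in hypermethylation. Hypomethylation replicate 1 was the shallowest library, and hypomethylation replicate 2 stood apart from its group: it lay at -56.0 on the second principal component, and its counts varied against those of the other 2 libraries with a chi-square per degree of freedom of 65.1 and 98.6, against 16 between those 2. Along the first component, which held 61.8% of the variance, controls lay between -73.0 and -66.0 and both strains between 27.9 and 47.9. Changes are given as log2 changes ± SE from edgeR over 12300 genes, with group means of normalised counts (CPM) ± SD, n = 3 libraries per group. Each single gene said to rise or fall had all 3 libraries of a group beyond all 3 of the other unless stated, a separation that chance gives in 10% of genes.

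Both transgenes were high in their own strain. The gene alkb-1 (CELE_Y51H7C.5, chromosome II, 1412404 to 1420314, WBcel235), which encodes an AlkB-family demethylase, was 52.1-fold higher in hypomethylation than in control, at 1434 ± 412 against 27.5 ± 2.68 CPM (log2 change 5.70 ± 0.23, adjusted p = 6.1e-08). In hypermethylation it was at 38.2 ± 3.37 CPM, a log2 change of 0.47 ± 0.19 that missed the threshold (adjusted p = 0.0752). The gene damt-1 (CELE_C18A3.1, chromosome II, 5720148 to 5721795), which encodes a putative adenine methyltransferase, was at 110 ± 2.35 CPM in hypermethylation against 2.86 ± 0.82 in control (log2 change 5.27 ± 0.17, adjusted p = 9.1e-09). In hypomethylation damt-1 was at 2.2 ± 0.31 CPM (log2 change -0.32 ± 0.21, adjusted p = 0.254), and this value turned positive when libraries were scaled by their totals. Exact two-sided permutation tests of 3 against 3 libraries gave p = 0.1, the smallest they allow, for each gene in its own strain. They gave the same value for alkb-1 in hypermethylation against control, so they do not single out the strain overexpressing alkb-1. The span of damt-1 overlaps another gene on the opposite strand, and the labels do not say whether the libraries keep the strand.

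**Figure D1:**
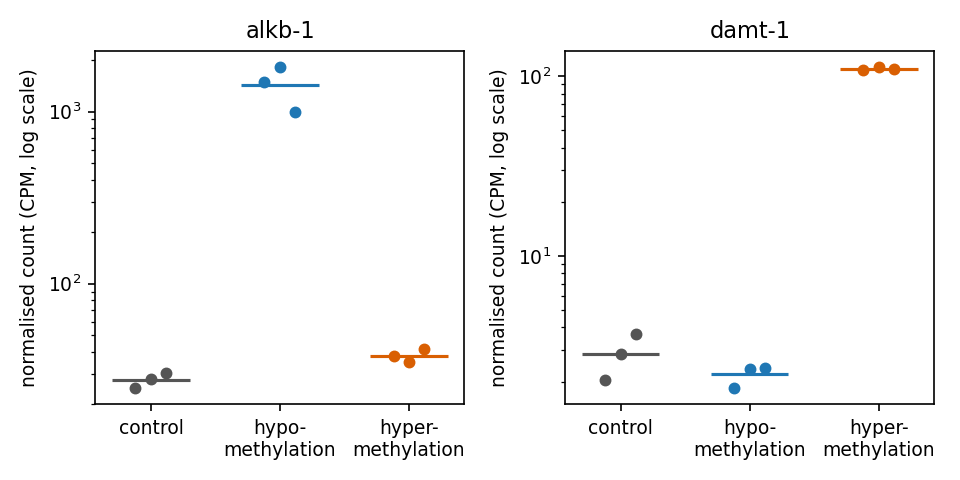
Normalised counts (CPM, log axis) of alkb-1 and damt-1 in each of the 3 libraries of the 3 groups; lines mark group means. The 3 hypomethylation libraries lie between 1001 and 1821 CPM for alkb-1, and the 3 hypermethylation libraries between 108 and 113 CPM for damt-1.

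Hypomethylation against control asks what differs in the strain overexpressing alkb-1, which the labels name for a lowered mitochondrial mark. Genes of the cuticle and of moulting were far higher in the hypomethylation strain, and the yolk protein genes far lower. Of 19 moulting genes, 15 rose and 0 fell, with a median change of 12.4-fold (15 and 0 adjusted over the list alone). On the log2 scale that median was 3.64, and under 6 other scalings it lay between 2.0 and 4.0. Among them mlt-8 (CELE_W08F4.6, chromosome II, 569210 to 577746) rose from 14.8 ± 1.84 to 349 ± 25.3 CPM (log2 change 4.56 ± 0.13, adjusted p = 9.7e-09). The gene qua-1, which encodes a hedgehog-related protein required for moulting, rose by 4.42 ± 0.19. The list test (camera) gave an adjusted p of 1.7e-15, and adjusted p = 0.0385 with an estimated correlation. Of 56 hedgehog-related and patched-related genes, 40 rose and 6 fell (40 and 9 adjusted over the list alone), with a median of 3.66-fold (adjusted p = 3.7e-12, and adjusted p = 0.0115 with an estimated correlation). The patched-related ptr-2 rose by 4.44 ± 0.18 and grd-1 by 2.83 ± 0.14. Of 140 cuticle collagens, 79 rose and 30 fell (80 and 34 adjusted over the list alone), with a median of 3.93-fold (adjusted p = 8.0e-12, but adjusted p = 0.504 with an estimated correlation). The collagen dpy-13 (CELE_F30B5.1, chromosome IV, 4235614 to 4236710) rose from 48.3 ± 9.58 to 1303 ± 167 CPM, and sqt-1 from 15.7 ± 1.00 to 382 ± 30.9 CPM.

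All 6 vitellogenins, the yolk protein genes that the adult intestine expresses, fell in the hypomethylation strain (6 adjusted over the list alone). Tested together they passed with a median log2 change of -3.83 (adjusted p = 2.6e-05, but adjusted p = 0.504 with an estimated correlation). The gene vit-6 (CELE_K07H8.6, chromosome IV, 8261134 to 8266459) was at 2226 ± 1392 CPM against 26870 ± 2960 in control, a log2 change of -3.59 ± 0.44. Together the 6 genes took 7.60% ± 0.804 of all counts in control, 0.740% ± 0.417 in hypomethylation and 2.17% ± 0.248 in hypermethylation. Exact permutation tests of each strain against control gave p = 0.1, the smallest they allow. The lowest share, 0.272%, was in hypomethylation replicate 2.

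**Figure D2:**
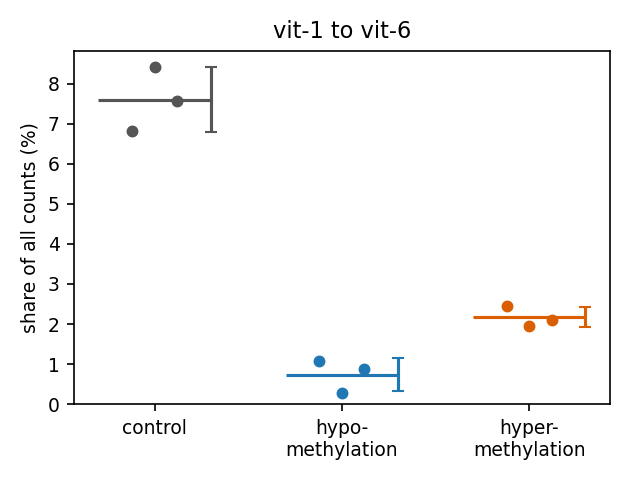
Share of all counts (%) taken by the 6 vitellogenins in each library; lines mark group means and bars the SD over 3 libraries. Control libraries lie between 6.81% and 8.41%, hypomethylation between 0.272% and 1.07%, and hypermethylation between 1.96% and 2.44%.

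Nuclear genes for mitochondrial ribosomal proteins were also higher in the hypomethylation strain. Of 68 mitochondrial ribosomal protein genes, 46 rose and 0 fell (47 and 1 adjusted over the list alone), with a median of 1.42-fold (adjusted p = 1.7e-04, but adjusted p = 0.504 with an estimated correlation). The genes mrps-22 and mrpl-49 rose by 1.01 ± 0.13 each. Of 14 genes of the mitochondrial unfolded protein response, 9 rose and 0 fell (9 and 1 adjusted over the list alone). The list missed the threshold (adjusted p = 0.0706) but was called under 3 of 6 other scalings. Its members hsp-6 (CELE_C37H5.8, chromosome V, 4824124 to 4826760), the mitochondrial HSP70, and hsp-60 (CELE_Y22D7AL.5, chromosome III, 1619742 to 1625803), the mitochondrial chaperonin, rose 2.59-fold and 2.49-fold. The level of hsp-6 was 397 ± 111 against 153 ± 12 CPM (log2 change 1.37 ± 0.18, adjusted p = 1.6e-04), and that of hsp-60 was 306 ± 69.0 against 123 ± 3.38 CPM (1.32 ± 0.15, adjusted p = 6.8e-05). The import channel gene timm-23 rose by 0.80 ± 0.15 and the Lon protease gene lonp-1 by 0.68 ± 0.13. Of 5 genes for mitochondrial DNA replication and expression, 4 rose (5 adjusted over the list alone). The list itself missed the threshold (adjusted p = 0.105). Among the risen, hmg-5, the mitochondrial DNA packaging protein gene, was at 1.45 ± 0.24 and the mitochondrial RNA polymerase gene rpom-1 at 1.08 ± 0.22. Of 31 proteasome genes, 25 rose and 0 fell (25 adjusted over the list alone). The list test passed with a median of 1.33-fold (adjusted p = 0.0135, but adjusted p = 0.504 with an estimated correlation), with rpn-11 at 0.57 ± 0.09.

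**Figure D3:**
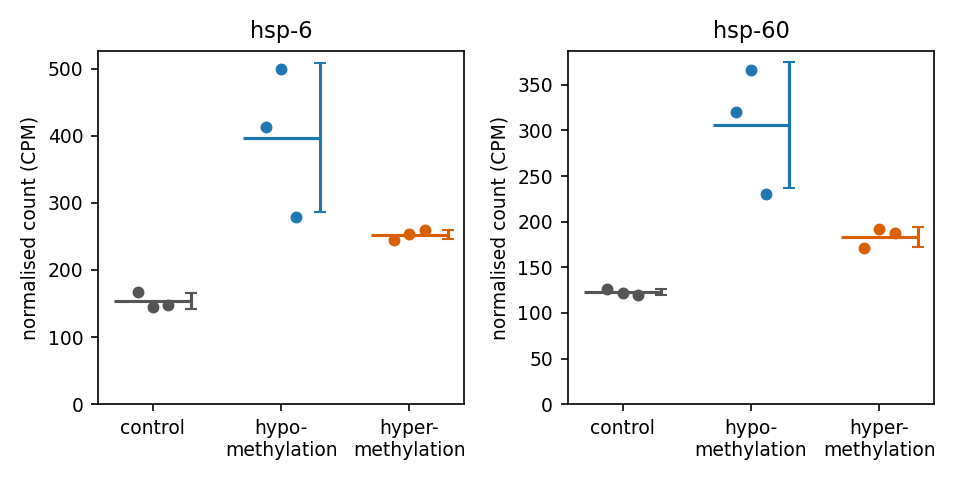
Normalised counts (CPM) of hsp-6 and hsp-60 in each library; lines mark group means and bars the SD over 3 libraries. For hsp-6 the control libraries lie between 145 and 167 CPM, hypomethylation between 279 and 499, and hypermethylation between 245 and 259.

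Genes of fatty acid synthesis and of glycolysis were lower in the hypomethylation strain. Of 18 genes of fatty acid synthesis, desaturation and elongation, 10 fell and 0 rose (11 and 0 adjusted over the list alone). Together these genes passed with a median log2 change of -0.46 (adjusted p = 0.0112, but adjusted p = 0.504 with an estimated correlation). That call was kept under 5 of 6 other scalings, with as few as 4 members lower. The elongases elo-5 and elo-6, which act on branched-chain fatty acids, changed by -1.21 ± 0.12 and -0.90 ± 0.12. Of 17 glycolysis genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone). As a list they passed with a median of -0.42 (adjusted p = 0.0286, but adjusted p = 0.546 with an estimated correlation and 0.0710 without hypomethylation replicate 3), with the pyruvate kinase gene pyk-1 at -0.69 ± 0.10. The glycolysis call was kept under 4 of 6 other scalings, with as few as 3 members lower and as many as 2 higher. For the nuclear genes of complex I (8 fell and 1 rose of 26, median -0.23, adjusted p = 0.0706), complexes II to IV (8 fell of 20, median -0.26, adjusted p = 0.102), ATP synthase (5 fell and 1 rose of 13, median -0.29, adjusted p = 0.244) and the TCA cycle (9 fell of 25, median -0.30, adjusted p = 0.0643), the lists missed the threshold and each median turned positive when libraries were scaled by their totals. Adjusted over the list alone, 7, 10, 6 and 9 of their members were lower and 1, 0, 1 and 0 higher. Scaling by totals raised the median of all genes too, from 0.03 to 0.36. Relative to all genes, the TCA cycle median stayed lower under 6 of 6 other scalings (-0.33 to -0.03). Scalings that move all genes of a library alike can hardly change such a distance, here or for the lists below. The medians of complex I, complexes II to IV and ATP synthase turned higher than that of all genes only after quantile normalisation. Of 100 C-type lectins, 46 fell and 21 rose (48 and 22 adjusted over the list alone). Tested together they passed (adjusted p = 0.0074, but adjusted p = 0.623 with an estimated correlation and 0.117 without hypomethylation replicate 2). Of 81 F-box A genes, 21 fell and 5 rose (20 and 5 adjusted over the list alone), with a median of -0.26. The list passed (adjusted p = 0.0186, but adjusted p = 0.504 with an estimated correlation and 0.124 without hypomethylation replicate 2). The F-box A median turned positive when libraries were scaled by their totals. Relative to all genes it stayed lower, and the list call was kept, under 6 of 6 other scalings.

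The largest rises in the hypomethylation strain included genes without a count in any control library. Against a floor of 3 counts over the control group, the nuclear receptor gene nhr-265 was at least 74.7-fold higher, ttr-12 at least 64.9-fold and scl-10 at least 63.7-fold. The SCP-like gene scl-11 rose from 1.30 ± 0.246 to 173 ± 25.3 CPM. The collagen col-41 rose to 201 ± 321 CPM, a mean set by hypomethylation replicate 2, which had 571 CPM against 8.17 and 24.5 in the other 2 libraries. The lectin gene clec-97 and the insulin gene ins-31 had no count in any hypomethylation library and were at least 166-fold and 127-fold lower by the same floor. The superoxide dismutase gene sod-3 changed by -1.54 ± 0.15, in a list of 16 antioxidant enzymes of which 2 rose and 3 fell. Of 37 glutathione S-transferases, 15 fell and 2 rose (15 and 5 adjusted over the list alone). The list itself missed the threshold (adjusted p = 0.0744), with gst-20 at -0.63 ± 0.12. Its median of -0.14 turned positive when libraries were scaled by their totals, which raised the median of all genes as well. Relative to all genes it stayed lower under 6 other scalings (-0.16 to -0.13).

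The other lists missed the threshold in hypomethylation against control. More members rose than fell among endoplasmic reticulum unfolded protein response genes (6 and 0 of 16, with pdi-2 at 0.86 ± 0.13, but up to 12 higher under another scaling, with the list called under 3 of 6), cytosolic ribosomal proteins (6 and 0 of 79, but up to 72 higher under another scaling, with the list called under 3 of 6), cytosolic heat shock proteins (6 and 3 of 14), HIF-1 targets (3 and 0 of 8), cytochrome P450 genes (19 and 15 of 50), DNA repair genes (8 and 0 of 19, with mre-11 at 2.70 ± 0.42), histones (11 and 3 of 26, called under 1 of 6 other scalings) and methyl transferases and demethylases (2 and 0 of 6, alkb-1 included). Among the HIF-1 targets, phy-2, a collagen prolyl hydroxylase gene, rose by 1.40 ± 0.12. More fell than rose among UDP-glucuronosyltransferases (20 and 14 of 57), neuropeptides and insulins (18 and 15 of 129), fatty acid breakdown genes (6 and 5 of 20), mitochondrial dynamics and mitophagy genes (4 and 1 of 17) and DAF-16 targets (3 and 2 of 14). The median of each of these 5 lists turned positive when libraries were scaled by their totals, which raised the median of all genes as well. Relative to all genes, the medians of fatty acid breakdown genes and DAF-16 targets changed sign only after quantile normalisation. Those of the other lists kept their sign under 6 other scalings. Equal numbers rose and fell among lysozymes and saposin-like proteins (8 each of 29), pathogen response genes (5 each of 18) and intracellular pathogen response genes (4 each of 26). Scaling reversed the sign of each of these 3 medians, as it did for cytochrome P450 genes and HIF-1 targets. Relative to all genes, the medians of pathogen response genes and HIF-1 targets kept their sign. Of the cell type markers, 9 of 18 body wall muscle genes fell, with unc-27, troponin I, at -0.59 ± 0.12, and 5 fell and 2 rose of 14 intestinal genes; the muscle median turned positive without the 50 most abundant genes and the intestinal median when libraries were scaled by their totals. Among hypodermal genes 8 rose and 3 fell of 13, and among pharyngeal genes 3 rose and 5 fell of 14. Among neuronal genes 2 rose and 1 fell of 19, and among sperm genes 2 fell of 9. The pharyngeal, neuronal and sperm medians turned positive when libraries were scaled by their totals. Relative to all genes, the pharyngeal and sperm medians stayed lower under 6 other scalings. The neuronal and intestinal medians turned higher than that of all genes only after quantile normalisation. Of 26 germline markers 7 passed the filter and 5 rose, among them mex-3 by 2.22 ± 0.24. Median, mean and test differed in sign for lysozymes (median -0.19, mean 0.70), antioxidant enzymes (0.04 and -0.02), pharyngeal (-7.4e-04 and 0.44) and neuronal genes (-0.02 and 0.05), and for intracellular pathogen response genes, whose median of 0.04 and mean of 0.08 stood against a test directed down.

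Higher and lower members adjusted over the list alone differed from these counts for cytosolic ribosomal proteins (2 and 0), UDP-glucuronosyltransferases (16 and 20), DAF-16 targets (2 and 1), lysozymes (8 and 11), fatty acid breakdown (5 and 7), histones (12 and 3), neuropeptides (14 and 13), intestinal (2 and 6) and neuronal genes (1 and 1), and were the same for the other lists.

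In all, 2691 genes were higher and 2420 lower in hypomethylation than in control, of which 1477 and 830 changed at least 2-fold. The groups did not overlap for 49.5% of genes, against 10% by chance. Scaling decided the balance: scaled by library totals, the median of all genes moved from 0.03 to 0.36 and 80.8% of changed genes were higher, against 52.7%. Without hypomethylation replicate 1 the counts were 2676 higher and 2329 lower, and without replicate 2 they were 2548 and 2410.

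Hypermethylation against control asks what differs in the strain overexpressing damt-1, which the labels name for a raised mitochondrial mark. The same families led. Of 140 cuticle collagens, 88 rose and 18 fell (93 and 19 adjusted over the list alone), with a median of 4.0-fold (adjusted p = 7.6e-21, but adjusted p = 0.411 with an estimated correlation). The collagens dpy-13 and col-157 rose by 5.4 ± 0.19 and 5.25 ± 0.15, dpy-13 to 2037 ± 120 CPM. Of 56 hedgehog-related and patched-related genes, 42 rose and 5 fell (42 and 5 adjusted over the list alone), with a median of 4.62-fold (adjusted p = 6.8e-16, and adjusted p = 0.0105 with an estimated correlation). The gene ptr-2 (CELE_C32E8.8, chromosome I, 3789309 to 3792797) rose from 1.62 ± 0.26 to 66.9 ± 5.59 CPM. Of 19 moulting genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 3.24-fold (adjusted p = 3.8e-10, but adjusted p = 0.112 with an estimated correlation). The genes mlt-8 and nas-36 rose by 4.43 ± 0.13 and 4.37 ± 0.16. All 6 vitellogenins fell (6 adjusted over the list alone). The list test passed with a median of -2.43 (adjusted p = 0.0187, but adjusted p = 0.625 with an estimated correlation), with vit-5 at -2.25 ± 0.46.

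The lists of complex I, complexes II to IV, the TCA cycle and glycolysis were called lower in the hypermethylation strain, but all 4 calls were lost with an estimated correlation (adjusted p = 0.655, 0.653, 0.625 and 0.625). Their medians kept that sign under every scaling tried. Their lower members, however, numbered as few as 3, 5, 5 and 6 under another scaling, and the calls of the former 3 lists were each lost under 1 of 6 scalings. Of 26 nuclear complex I genes, 20 fell and 1 rose (21 and 1 adjusted over the list alone). Together these genes passed with a median of -0.33 (adjusted p = 0.0187, but adjusted p = 0.655 with an estimated correlation). Its subunit genes nduf-5 and D2030.4 changed by -0.64 ± 0.14 and -0.57 ± 0.12. Of 20 genes of complexes II to IV, 14 fell and 0 rose (16 and 0 adjusted over the list alone). As a list they passed with a median of -0.37 (adjusted p = 0.0358, but adjusted p = 0.653 with an estimated correlation), with ucr-11 at -0.71 ± 0.14. That call was lost without control replicate 1 (adjusted p = 0.0541), hypermethylation replicate 1 (0.0565) or hypermethylation replicate 3 (0.0520). Of 13 ATP synthase genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone), and the list missed the threshold (adjusted p = 0.121) but was called under 2 of 6 other scalings. Of 25 TCA cycle genes, 13 fell and 0 rose (14 and 0 adjusted over the list alone). The list test passed (adjusted p = 0.0187, but adjusted p = 0.625 with an estimated correlation), with the malate dehydrogenase gene mdh-1 at -0.78 ± 0.10. Of 17 glycolysis genes, 13 fell and 2 rose (13 and 2 adjusted over the list alone). Together these genes passed (adjusted p = 0.0187, but adjusted p = 0.625 with an estimated correlation), with the glyceraldehyde-3-phosphate dehydrogenase gene gpd-3 at -0.98 ± 0.12. Of 18 genes of fatty acid synthesis, 13 fell and 1 rose (15 and 1 adjusted over the list alone). This family passed as a list (adjusted p = 0.0072, but adjusted p = 0.625 with an estimated correlation). Its desaturase genes fat-2 and fat-4 changed by -0.98 ± 0.11 and -0.97 ± 0.10.

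**Figure D4:**
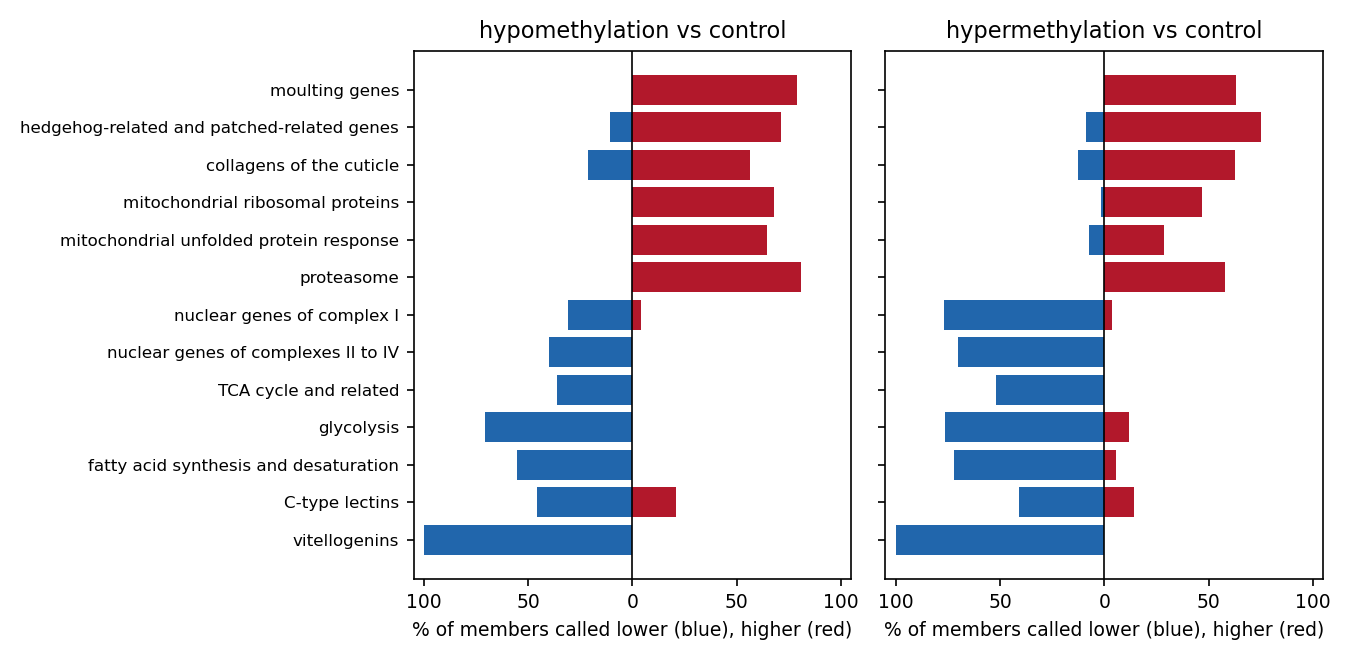
Share of tested members (%) of 13 gene lists called higher (red) or lower (blue) in each strain against control. In hypomethylation, 15 of 19 moulting genes were higher and 6 of 6 vitellogenins lower; the lower shares of complex I, complexes II to IV and TCA cycle genes there come with medians that turned positive when libraries were scaled by their totals, which raised the median of all genes as well.

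Mitochondrial ribosomal protein genes were higher in hypermethylation as well: of 68, 32 rose and 1 fell (35 and 1 adjusted over the list alone). The list test passed with a median of 1.30-fold (adjusted p = 0.0254, but adjusted p = 0.625 with an estimated correlation and 0.0610 without control replicate 2). Of the 14 genes of the mitochondrial unfolded protein response, 4 rose and 1 fell (4 and 1 adjusted over the list alone). The list itself missed the threshold (adjusted p = 0.602). Its members hsp-6 and hsp-60 rose by 0.72 ± 0.18 (adjusted p = 0.00814) and 0.58 ± 0.15 (adjusted p = 0.0105), and dve-1, a transcriptional regulator of that response, by 0.81 ± 0.10. Of the 5 genes for mitochondrial DNA replication and expression, 4 rose (4 adjusted over the list alone). The list itself missed the threshold (adjusted p = 0.124), with the helicase gene twnk-1 at 1.53 ± 0.28 and hmg-5 at 1.39 ± 0.23. Of 31 proteasome genes, 18 rose and 0 fell (21 adjusted over the list alone). The list itself missed the threshold (adjusted p = 0.132), with pas-6 at 0.66 ± 0.11, but was called under 4 of 6 other scalings with 12 to 25 members higher.

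Of 100 C-type lectins, 41 fell and 14 rose in hypermethylation (42 and 15 adjusted over the list alone). Tested together they passed (adjusted p = 0.0072, but adjusted p = 0.625 with an estimated correlation), with clec-146 at -2.23 ± 0.16. Of 37 glutathione S-transferases, 14 fell and 6 rose (15 and 7 adjusted over the list alone). The list test passed (adjusted p = 0.0358, but adjusted p = 0.625 with an estimated correlation), with gst-4 at -1.2 ± 0.11. Their call was lost without hypermethylation replicate 1 (adjusted p = 0.0565) or hypomethylation replicate 2 (0.162), which enters through the shared estimate of spread. Of 129 neuropeptide and insulin genes, 34 fell and 12 rose (31 and 11 adjusted over the list alone). Together these genes passed (adjusted p = 0.0358, but adjusted p = 0.625 with an estimated correlation), with nlp-27 at -1.89 ± 0.19 and nlp-30, an antimicrobial peptide gene, at 3.46 ± 0.35. That call was lost without control replicate 1 (adjusted p = 0.0706), hypermethylation replicate 1 (0.0565) or hypomethylation replicate 2 (0.0712). Of 6 methyl transferase and demethylase genes, 3 rose (4 higher and 1 lower adjusted over the list alone). This family passed as a list (adjusted p = 0.0187, but adjusted p = 0.50 with an estimated correlation), and it holds the damt-1 transgene. That call was kept under 3 of 6 other scalings. Among single genes, scl-10 was at least 34.6-fold and ttr-12 at least 25.6-fold higher than the floor over the control group. The prion-like pqn-29 rose from 0.531 ± 0.312 to 39.5 ± 3.30 CPM, and dct-8 fell from 15.1 ± 3.87 to 0.763 ± 0.281 CPM. The gene sod-3 changed by -2.11 ± 0.15, in a list of 16 antioxidant enzymes of which 1 rose and 3 fell. The median of that list turned positive when libraries were scaled by their totals, which raised the median of all genes as well. Relative to all genes it stayed lower under 6 other scalings (-0.14 to -0.04).

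The other lists missed the threshold in hypermethylation against control. More members rose than fell among endoplasmic reticulum unfolded protein response genes (7 and 1 of 16, with enpl-1 at 0.67 ± 0.11, but up to 13 higher under another scaling, with the list called under 3 of 6), HIF-1 targets (4 and 1 of 8, with phy-2 at 1.55 ± 0.12), DNA repair genes (5 and 0 of 19) and histones (13 and 3 of 26, called under 1 of 6 other scalings). More fell than rose among UDP-glucuronosyltransferases (22 and 16 of 57, with ugt-41 at -1.57 ± 0.11), cytochrome P450 genes (17 and 12 of 50), DAF-16 targets (5 and 1 of 14), lysozymes and saposin-like proteins (14 and 5 of 29, called under 2 of 6 other scalings), pathogen response genes (6 and 4 of 18), F-box A genes (18 and 6 of 81, called under 1 of 6) and mitochondrial dynamics genes (5 and 1 of 17, with the autophagy gene bec-1 at -1.11 ± 0.14). Scaled by library totals, the medians of UDP-glucuronosyltransferases, DAF-16 targets, pathogen response, F-box A and mitochondrial dynamics genes turned positive, as did that of all genes. Relative to all genes, each of these list medians stayed lower under 6 other scalings. Equal numbers rose and fell among cytosolic heat shock proteins (3 each of 14), intracellular pathogen response genes (5 each of 26), fatty acid breakdown genes (5 each of 20) and cytosolic ribosomal proteins (1 each of 79, but up to 39 higher and the list called higher under 1 of 6 other scalings). Scaling reversed the median of each of these lists but fatty acid breakdown. Relative to all genes, only the cytosolic ribosomal median changed sign, after quantile normalisation. Of the cell type markers, 6 of 18 body wall muscle genes fell and 1 rose, 8 of 13 hypodermal genes rose and 2 fell, 5 of 14 pharyngeal genes rose and 4 fell, and 3 of 14 intestinal genes rose and 2 fell; the pharyngeal median turned negative after quantile normalisation. Among neuronal genes 1 rose and 2 fell of 19, among sperm genes 1 rose and 2 fell of 9, and of 7 germline genes 2 rose, mex-3 by 1.47 ± 0.24. The neuronal and sperm medians turned positive when libraries were scaled by their totals. Relative to all genes, the sperm and pharyngeal medians kept their sign, and the neuronal median changed sign only after quantile normalisation. Median, mean and test differed in sign for lysozymes (median -0.68, mean 0.07), fatty acid breakdown genes (0.09 and -0.03) and neuronal genes (-0.08 and 0.02), and for cytosolic heat shock proteins, whose median of 0.13 and mean of 0.04 stood against a test directed down.

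Higher and lower members adjusted over the list alone differed from these counts for cytosolic ribosomal proteins (1 and 0), endoplasmic reticulum genes (10 and 1), UDP-glucuronosyltransferases (18 and 23), cytochrome P450 genes (12 and 18), lysozymes (5 and 16), pathogen response genes (5 and 7), fatty acid breakdown (6 and 5), histones (14 and 4), F-box A (5 and 17) and muscle genes (1 and 7), and were the same for the other lists.

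In all, 2582 genes were higher and 2365 lower in hypermethylation than in control, of which 1350 and 863 changed at least 2-fold. The groups did not overlap for 60.1% of genes, against 10% by chance. Scaled by library totals, the median of all genes moved from -0.01 to 0.21 and 71.6% of changed genes were higher, against 52.2%. Without hypomethylation replicate 2, which enters through the shared estimate of spread, the counts were 3074 higher and 2952 lower. Fitted on the 6 libraries of the 2 groups alone, 6479 genes were called, against 4072 for hypomethylation against control fitted in that way. The totals of the 2 strains against control are therefore not a ranking of the strains.

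Hypermethylation against hypomethylation tests whether the 2 strains differ from each other. Collagens were higher in hypermethylation: of 140, 52 rose and 19 fell (64 and 25 adjusted over the list alone), with a median of 2.08-fold (adjusted p = 7.0e-07, but adjusted p = 0.933 with an estimated correlation). The collagen col-155 rose from 146 ± 14.6 to 677 ± 58.5 CPM. Of 6 vitellogenins, 4 were higher in hypermethylation (6 adjusted over the list alone). Together these genes passed with a median of 3.25-fold (adjusted p = 0.0185, but adjusted p = 0.933 with an estimated correlation), with vit-6 at 1.79 ± 0.41. Of 56 hedgehog-related and patched-related genes, 20 rose and 9 fell (21 and 13 adjusted over the list alone). As a list they passed (adjusted p = 0.0357, but adjusted p = 0.933 with an estimated correlation), with ptr-3 at 2.17 ± 0.19. That call was lost without control replicate 1 (adjusted p = 0.0602), hypermethylation replicate 1 (0.0816) or hypomethylation replicate 3 (0.0782). The moulting genes split: 9 of 19 were lower and 4 higher (list adjusted p = 0.104), with fbn-1 at -3.56 ± 0.32 and noah-2 at -2.38 ± 0.30 against nas-36 at 1.73 ± 0.14 and mlt-7 at 1.57 ± 0.13. Of the 14 pharyngeal genes, 6 rose and 0 fell (6 adjusted over the list alone). The list test passed (adjusted p = 0.0307, but adjusted p = 0.933 with an estimated correlation), with phat-4 at 1.30 ± 0.10, and the call was lost without hypermethylation replicate 3 (adjusted p = 0.0576), hypomethylation replicate 2 (0.0506) or hypomethylation replicate 3 (0.0849, with the median at -0.07). It was kept under 2 of 6 other scalings.

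The mitochondrial chaperonin gene hsp-60 was lower in hypermethylation than in hypomethylation, at 184 ± 10.9 against 306 ± 69.0 CPM (log2 change -0.74 ± 0.15, adjusted p = 0.00546), and dve-1 was higher by 0.62 ± 0.10. Of the 14 genes of that response 6 were lower and 2 higher (list adjusted p = 0.0882). Of 79 cytosolic ribosomal protein genes, 6 were lower and 0 higher (2 and 0 adjusted over the list alone), and up to 57 were lower under another scaling. Tested together they passed with a median of -0.24 (adjusted p = 0.010, but adjusted p = 0.933 with an estimated correlation and 0.0943 without hypomethylation replicate 1), with rpl-11.1 at -0.90 ± 0.11. Of 29 lysozyme and saposin-like genes, 9 were lower and 1 higher (10 and 1 adjusted over the list alone). Together these genes passed (adjusted p = 0.0158, but adjusted p = 0.933 with an estimated correlation and 0.113 without hypomethylation replicate 3), with lys-7 at -1.36 ± 0.22. Of 50 cytochrome P450 genes, 14 were lower and 11 higher (15 and 13 adjusted over the list alone; median -0.09, mean -0.55; adjusted p = 0.0210, but adjusted p = 0.933 with an estimated correlation and 0.0532 without hypomethylation replicate 2, where the median was 0.02). The cytochrome P450 call was kept under 3 of 6 other scalings. Between the strains nas-21 and clec-97, both without a count in hypomethylation, were at least 41.8-fold and 31-fold higher in hypermethylation against the floor over the hypomethylation group.

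Between the strains the lists of energy metabolism missed the threshold: 0 of 26 complex I, 1 of 20 complexes II to IV, 0 of 13 ATP synthase and 0 of 25 TCA cycle genes passed (list adjusted p = 0.503, 0.523, 0.641 and 0.567). This depends on the scaling: of 6 others, 2 called complex I lower in hypermethylation (up to 7 members), 2 called complexes II to IV lower (up to 11) and 1 called ATP synthase lower (up to 7). The members that passed, higher and lower, were for mitochondrial ribosomal proteins (0 and 6 of 68), mitochondrial DNA replication genes (0 and 0 of 5), proteasome genes (0 and 2 of 31), DNA repair genes (0 and 0 of 19), histones (1 and 1 of 26), glycolysis genes (1 and 3 of 17), mitochondrial dynamics genes (0 and 2 of 17), antioxidant enzymes (0 and 3 of 16), cytosolic heat shock proteins (0 and 2 of 14) and HIF-1 targets (1 and 0 of 8). Further counts, in the same order, were for UDP-glucuronosyltransferases (17 and 15 of 57, with ugt-44 at 1.73 ± 0.12), C-type lectins (14 and 15 of 100), F-box A genes (11 and 6 of 81), intracellular pathogen response genes (6 and 8 of 26), neuropeptides and insulins (4 and 18 of 129), glutathione S-transferases (3 and 7 of 37) and pathogen response genes (5 and 3 of 18). The same counts for the remaining lists were: fatty acid synthesis (3 and 4 of 18), fatty acid breakdown (4 and 3 of 20), endoplasmic reticulum unfolded protein response (2 and 3 of 16), DAF-16 targets (1 and 4 of 14) and methyl transferases and demethylases (1 and 2 of 6). Under 6 other scalings mitochondrial ribosomal proteins and neuropeptides (up to 29 lower) were each called lower under 3, mitochondrial unfolded protein response and proteasome genes under 2 and antioxidant enzymes under 1. Scaling reversed the medians of endoplasmic reticulum genes, UDP-glucuronosyltransferases, HIF-1 targets, C-type lectins, F-box A, sperm and muscle genes. Relative to all genes, of these only the medians of endoplasmic reticulum genes and C-type lectins changed sign. Among cell type markers, 6 intestinal genes were higher and 1 lower of 14, with elt-2, an intestinal GATA factor gene, at 0.75 ± 0.13. The values were 1 and 0 of 18 for body wall muscle, 2 and 3 of 13 for hypodermis, 0 and 0 of 19 for neuron, 0 and 1 of 9 for sperm and 0 and 1 of 7 for germline. Median, mean and test differed in sign for endoplasmic reticulum genes (median 0.05, mean -0.04), C-type lectins (-0.04 and 0.23), fatty acid breakdown genes (-0.01 and 0.03) and histones (-0.12 and 0.0047), and for methyl enzymes (-0.19 and -0.03) and mitochondrial DNA replication genes (-0.06 and -0.01), whose tests were directed up.

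Higher and lower members adjusted over the list alone differed for moulting (4 and 10), mitochondrial unfolded protein response (2 and 10), complexes II to IV (0 and 0), mitochondrial ribosomal (0 and 3), proteasome (0 and 0), histone (0 and 0), mitochondrial dynamics (0 and 1), antioxidant (0 and 2) and UDP-glucuronosyltransferase genes (18 and 15). They also differed for C-type lectins (15 and 16), neuropeptides (4 and 13), glutathione S-transferases (3 and 8), pathogen response (5 and 6), fatty acid synthesis (4 and 6), germline (0 and 2), sperm (0 and 0) and hypodermal genes (3 and 4), and were the same for the other lists.

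In all, 1546 genes were higher and 1296 lower in hypermethylation than in hypomethylation, of which 611 and 584 changed at least 2-fold. The groups did not overlap for 39.2% of genes, against 10% by chance. Scaled by library totals, the median of all genes moved from -0.03 to -0.14 and 37.9% of changed genes were higher, against 54.4%. Without hypermethylation replicate 2 the counts were 1014 higher and 803 lower.

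The differences of the 2 strains from control were largely shared. Against control, 1785 genes were higher in both strains, where 565 would be shared if the calls were independent, and 1493 were lower in both, where 465 would be. Across genes the log2 changes had a correlation of 0.80 and a covariance of 1.26, against 0.518 and 0.0544 on average in 20 simulated data sets in which unchanged groups shared the control libraries. Genes are not independent replicates, and both comparisons use the same 3 control libraries, which are too few to be divided between them. A difference particular to the control libraries would be shared in the same way, and the simulated data hold none. If the control animals carry no transgene, an effect of carrying any transgene would be shared too. The overlap therefore does not tell a response to alkb-1 or damt-1 from such an effect or from a trait of the controls. The rises shared by both strains with the largest smaller change were scl-10, ttr-12, dos-2, clec-230 and col-131, which rose by 5.60 ± 0.44 in hypomethylation and 6.34 ± 0.42 in hypermethylation. The falls so chosen were scl-15, nspf-3, dct-8, fipr-18 and clec-197, with dct-8 at -4.01 ± 0.41 and -4.31 ± 0.41.

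Genes called in opposite directions against control numbered 102, where 1025 would be if the calls were independent. They are not, since the shared controls alone gave a correlation of 0.518 on average in simulated data. Of these, 47 were higher in hypomethylation and lower in hypermethylation, and 55 the reverse. The cytochrome P450 gene cyp-13A5 (CELE_T10B9.2, chromosome II, 9798277 to 9800413) was at 56.1 ± 11 CPM in hypomethylation, 9.85 ± 1.55 in control and 3.44 ± 0.173 in hypermethylation. It changed by 2.52 ± 0.17 and -1.51 ± 0.19 against control, and by -4.03 ± 0.19 between the strains. The fatty acid and retinol binding protein gene far-3 changed by 1.68 ± 0.19 and -1.2 ± 0.19, and cyp-14A1 by 1.09 ± 0.24 and -2.03 ± 0.27.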

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

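The tests of hypomethylation replicate 2 and of a general rise of mitochondrial genes on hsp-6 and hsp-60, and the scaling test of the hypermethylation strain alone, were chosen after the result was seen. Scaling by library totals, leaving out the 50 most abundant genes and the developmental gene lists, with their values without single libraries, were also chosen after seeing the data.

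A difference between the strains drew attention to 102 genes that were called in opposite directions against control and also called in the direct test between the strains, among them cyp-13A5, far-3 and cyp-14A1. Without hypomethylation replicate 2 they numbered 169, without control replicates 1, 2 and 3 they numbered 51, 52 and 52, and without hypermethylation replicate 2 they numbered 62. A gene called on opposite sides of the same controls is almost bound to differ between the strains, so the direct test adds little.

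Moulting genes were higher and vitellogenins lower in both strains. A shift in scaling from the abundant transcripts of the control libraries is argued against by the median of the moulting list itself. Its lowest value under 6 other scalings was 2.00 (log2) in hypomethylation and 1.28 in hypermethylation. It also stayed at least 1.38 above the median of all genes in both strains, but scalings that move all genes alike could not change that distance. The shallow library is argued against too, since 16 moulting genes were still called without hypomethylation replicate 1. An earlier developmental stage of the strains' animals may contribute: DNA replication and cell division genes, a list not used before, had median changes of 2.14 in hypomethylation (1.76 without hypomethylation replicate 2) and 1.21 in hypermethylation, though 5 of 7 germline markers (mex-3 by 2.22; 3 of 7 without control replicate 1, control replicate 2 or hypomethylation replicate 2) and 2 of 7 rose beside them. The adult collagen gene col-19 fell in hypomethylation (-3.12 ± 0.91, adjusted p = 0.0178; -2.55 without hypomethylation replicate 2) and was at -1.72 ± 0.86 in hypermethylation (adjusted p = 0.138), while col-7 was at -0.96 ± 0.85 and 0.52 ± 0.84 (adjusted p = 0.401 and 0.661), but without hypomethylation replicate 2 hypermethylation had col-19 called lower (adjusted p = 2.7e-10) and col-7 called higher (0.0321), and of the genes that time larval development lin-28 was at -0.37 and -0.46 and lin-41 higher in hypomethylation (2.53, but 1.74 without hypomethylation replicate 2). With all 9 libraries, the other genes of that kind tested, lin-14, daf-12, lin-46, lin-29 and hbl-1, were called in neither strain against control. That did not hold throughout. In hypomethylation against control, 2 of the 7 genes were higher without hypomethylation replicate 1 or 3. Without hypomethylation replicate 2, 1 was higher and 2 were lower. Stage and an effect of the transgenes cannot be told apart here, because every library of a group shares its strain and the labels give L4 as the stage of every sample.

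The genes hsp-6 and hsp-60 were higher in the hypomethylation strain. Without hypomethylation replicate 2 both were still called, at 1.17 ± 0.13 and 1.16 ± 0.12, which argues against that library as the source. A rise common to all nuclear genes for mitochondrial proteins is argued against by the 59 respiratory chain and ATP synthase genes, whose median change was -0.25 against a mean of 1.35 for hsp-6 and hsp-60. Part of these genes did rise, with medians of 0.51 for mitochondrial ribosomal proteins (46 of 68 higher) and 0.83 for mitochondrial DNA replication and expression (4 of 5 higher, a list that missed the threshold), so a rise limited to some classes stays open. An effect of the transgene and a difference in stage, if there was one, stay open too, and neither was tested on these genes.

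The pooled genes of the respiratory chain, ATP synthase, TCA cycle and glycolysis had a negative median in both strains, but in hypomethylation only the glycolysis list was called (lost with an estimated correlation, adjusted p = 0.546, and without hypomethylation replicate 3, adjusted p = 0.0710) and 42 of 101 genes passed as lower. For hypomethylation the scaling of the libraries could account for the sign: scaled by library totals, the median of the 101 genes was 0.047 in place of -0.28, and although it then stayed 0.317 below the median of all genes, it was 0.0556 above it after quantile normalisation. For hypermethylation the scaling is argued against as the whole cause, since the median was at most -0.15 under 6 other scalings. A difference in stage and an effect of the transgenes stay open for both.

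For the numbers of changed genes, the 6 libraries of a pair of groups can be split in only 10 ways, too few for a share under 0.05. Fitted on those 6 libraries alone with edgeR, the real split gave 4072 genes for hypomethylation against control, 6479 for hypermethylation against control and 2183 between the strains. It was the 1 split of 10 with so many in each case, and the highest of the other splits gave 0. Every other split mixes libraries of the 2 groups, so their difference adds to the spread within each side. The 0 was therefore likely in advance and decides nothing about chance.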

How the results depend on the processing

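For named genes, 479 results were recomputed 11400 times in all. Direction and call were kept 10803 times, 572 lost the call, 12 gained it and 13 changed direction, and the cause was not tested. Apart from alkb-1 and damt-1, only results already called were recomputed, and these genes were named for a large change or a small adjusted p. The kept share is high in part for that reason, and the 12 gained calls can only belong to alkb-1 or damt-1. Scaling by library totals and leaving out the 50 most abundant genes were chosen after seeing the data. Alternatives on mitochondrial DNA transcripts were not run.

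Changed genes in hypomethylation against control, higher and lower, numbered 4334 and 1200 with limma on log2(FPKM + 1), 4333 and 1170 with a pseudocount of 0.1, 4332 and 1187 with 0.5, 4307 and 1141 without trend, 4351 and 1176 with a robust fit, and 4722 and 1125 by library totals; TPM gave 1251 lower. For hypermethylation the lower genes numbered 1384, 1329, 1366, 1309, 1378, 1382 and 1323 under the same settings. Genes lower in both strains numbered 714, 647, 689, 674, 699, 713 and 728, genes higher in both 2731 by library totals, and opposite genes 67 without trend. Of the genes called in hypomethylation, limma on log2(FPKM + 1) still called 75.5%, and DESeq2 98.3%. With a 2-fold minimum the counts were 1477 and 830, 1350 and 863, and 611 and 584.

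Lists higher in hypomethylation numbered 8 under the limma settings on FPKM and TPM, 10 without a filter and 9 (with 3 lower) after quantile normalisation. Lists higher in hypermethylation numbered 8 without a filter and after quantile normalisation. Lists lower between the strains numbered 8 under the limma settings on FPKM, 5 without a filter and 10 after quantile normalisation. With an estimated correlation, 2, 1 and 0 lists were higher and 0, 0 and 0 lower in the 3 comparisons.

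Among genes, ftn-1 in hypomethylation, at -0.32 in edgeR, was 0.0014 under limma on log2(FPKM + 1), without trend or robust, 0.0013 with the other pseudocounts and 0.025 by library totals, where damt-1 was 0.040 against -0.32 in edgeR. After quantile normalisation T27E9.2 was 0.12 (edgeR -0.39), cox-6C 0.044 (-0.40), T02H6.11 0.067 (-0.36), atp-3 0.0059 (-0.38) and R04F11.2 0.021 (-0.40) in hypomethylation, and rpl-43 was 0.40 (-0.53) in hypermethylation.

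With the replicate number as a block, the counts were 2472 and 2241, 2432 and 2134, and 1390 and 1063. The numbers showed no sign of pairing the libraries: after subtracting group means, 0 of 9 pairs with the same number across groups correlated above 0.1. With 3 libraries per group, this cannot exclude that the numbers mark matched cultures.

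Leaving out each library, hypomethylation counts ranged from 2231 to 2917 higher and 1903 to 2549 lower, hypermethylation from 2092 to 3074 and 1726 to 2952, and the strains from 1014 to 1910 and 803 to 1686. Genes higher in both ranged from 1454 to 1895, lower in both from 1079 to 1687, and opposite from 51 to 169. Lists ranged from 5 to 9 higher and 4 to 10 lower, from 4 to 6 and 6 to 9, and from 2 to 4 and 3 to 4. The log2 change of alkb-1 ranged from 5.49 to 5.90 and that of damt-1 from 5.08 to 5.48. Hypomethylation lists numbered 9 and 10 without hypomethylation replicate 1 and 8 higher without its replicate 3; between the strains 2 lists were higher without hypomethylation replicate 3, and 851, 803 and 862 genes lower without hypermethylation replicates 1, 2 and 3. In simulated data 1.5-fold changes were mostly missed. Far fewer genes changed there than were called in the real data, so that share does not carry over.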

Other observations

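The tests of Gene Ontology terms and of DNA replication and heterochronic genes were chosen after the result was seen. Gene Ontology terms for the cuticle and for rRNA processing were higher in both strains. Of 335 Gene Ontology terms tested with camera, 9 were higher in hypomethylation and 6 in hypermethylation, and 0 were lower in either; between the strains 0 were called, and 0 were called anywhere with an estimated correlation. Cuticle, moulting and matrix terms made up 5 of the 9 and 4 of the 6. Of 31 cuticle development genes, 18 rose and 7 fell in hypomethylation (adjusted p = 6.1e-05, but adjusted p = 0.997 with an estimated correlation) and 17 rose and 5 fell in hypermethylation (adjusted p = 1.9e-05, but adjusted p = 1.00 with an estimated correlation). Of 39 rRNA processing genes, 27 rose and 0 fell in hypomethylation (median 0.66, adjusted p = 0.0045, but adjusted p = 0.997 with an estimated correlation), and 23 rose and 0 fell in hypermethylation (median 0.68, adjusted p = 0.0164, but adjusted p = 1.00 with an estimated correlation). All 13 genes for formation of the cytoplasmic translation initiation complex rose in hypomethylation (adjusted p = 0.0112, but adjusted p = 0.997 with an estimated correlation), as did 29 of 62 spliceosomal mRNA splicing genes (adjusted p = 0.0319, but adjusted p = 0.997 with an estimated correlation). All 13 initiation complex genes rose in hypermethylation as well, but the term missed the threshold (adjusted p = 0.118), and the splicing and DNA replication terms were not called there. Of 10 genes for large ribosomal subunit biogenesis, 8 rose in each strain, and the term was called in hypermethylation (adjusted p = 0.0249, but adjusted p = 1.00 with an estimated correlation) and missed the threshold in hypomethylation (adjusted p = 0.0521).

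Of 27 DNA replication and cell division genes tested, 24 rose in hypomethylation, and 22 without hypomethylation replicate 2. Their levels varied within that strain, with mcm-7 at 11.3 ± 7.96 CPM and rnr-2 at 45.4 ± 21.2 CPM. In hypermethylation 16 rose, but 9 without control replicate 3. Between the strains 12 were lower in hypermethylation, but 6 without hypomethylation replicate 2, 6 without hypermethylation replicate 2 and 7 without hypermethylation replicate 3. Germline markers moved with them, in a background in which germ cells arrest: of 7 tested, 5 rose in hypomethylation (3 without control replicate 1, control replicate 2 or hypomethylation replicate 2) and 2 in hypermethylation, with glh-1 at 0.67 ± 0.14 and 0.68 ± 0.14. The ribonucleotide reductase gene rnr-1 rose by 3.73 ± 0.23 and 2.70 ± 0.23 against control, and the replication clamp gene pcn-1 by 1.98 ± 0.21 and 0.79 ± 0.21 (the latter call lost without control replicate 1, adjusted p = 0.0546). Of 7 heterochronic genes, which time larval development, lin-41 was at 38.0 ± 26.4 CPM in hypomethylation against 6.68 ± 2.85 in control (2.53 ± 0.46). Without hypomethylation replicate 2 that change was 1.74 (adjusted p = 2.4e-04), and lin-41 was then called higher in hypermethylation too (0.89, adjusted p = 0.0108). It was lower in hypermethylation than in hypomethylation (-1.64 ± 0.43, and -0.85 without hypomethylation replicate 2), but not called without hypermethylation replicate 1 or 2 (adjusted p = 0.0699 and 0.0740). The gene hbl-1 was also called lower in hypermethylation than in hypomethylation (-0.88 ± 0.24, adjusted p = 0.0213). Without hypermethylation replicate 1 or 2, 0 of the 7 heterochronic genes were called between the strains. The gene lin-28 was called lower in both strains, at -0.37 ± 0.13 and -0.46 ± 0.13 against control. The former call was lost without control replicate 1, 2 or 3 (adjusted p = 0.0661, 0.0839 and 0.105), hypomethylation replicate 1 or 3 (0.0920 and 0.0502) or hypermethylation replicate 3 (0.0546). The latter was lost without hypermethylation replicate 1 or 3 (0.0593 and 0.0551).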
